A study of Mus musculus with 9 samples.

How the data were processed

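RNA was measured in 9 libraries of green fluorescent cortical cells taken from mice at postnatal day 5. Per the labels, the cells came from 3 Cre lines crossed to the fluorescent reporter Ai47, with 3 libraries per line: VIP-Cre, SOM-Cre and Nkx2.1-CreER, the last with tamoxifen on embryonic day 17. The protocol in the labels describes slicing of fresh brains, dissection of layer 2/3 strips of the medial prefrontal and anterior cingulate cortex, digestion with Pronase E and DNase I, and picking of 150 fluorescent cells by hand for a sample. Total RNA was then extracted with a column kit, and libraries were prepared for Illumina sequencing, per the same labels. The libraries are called Nkx2.1, SOM and VIP libraries here, with the sample number of the label as the replicate number.

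The deposited values are raw read counts per gene symbol, 1 table per library. TopHat2 2.0.9, DESeq2 and the mouse build mm10 are named in the submitters' processing notes, with no role or order. The counting program, its strand setting and the DESeq2 version are not given in the sources used here. Reads of a gene and of a gene overlapping it on the other strand may therefore not be separable. Each table held 23319 gene symbols and 5 summary entries that name no gene, and these entries were kept out of library sizes and tests. They held 83.6% to 85.2% of the total of each table: 64.5% to 68.0% for alignments that were not unique, 16.4% to 18.2% for reads outside genes and 0.700% to 0.802% for ambiguous reads. Genes received 45.4% to 46.9% of the unique alignments. Reads in genes ranged from 6484488 to 12465997 per library, so that 3 reads, the floor used here, came to 0.248 to 0.447 CPM.

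Differential expression was tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 on the counts as deposited. All 9 libraries entered 1 fit with the group as the only term, TMM normalization and the filterByExpr filter by group at its default minimum count of 10. After the filter 10728 genes remained, and Benjamini-Hochberg adjustment was over these genes within a comparison, with a threshold of 0.05. The fit had 6 residual degrees of freedom and a common biological coefficient of variation of 1.40. The comparisons were Nkx2.1 against SOM, Nkx2.1 against VIP and SOM against VIP, and the genes past the threshold with the same sign against both SOM and VIP. Levels are given as CPM, the counts scaled to a common total of reads in genes after TMM normalization, as mean ± SD of 3 libraries, and fold changes as fitted log2 values with a standard error (SE). This SE was computed back from the test, as the size of the log2 value over the square root of its quasi-likelihood F statistic.

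Folds of other genes are ratios of the mean CPM. For a gene without a read in a group, the fold is a lower bound set by 3 reads over the group, from reads pooled over the libraries of each group. For a gene with 1 to 3 reads in a group, the ratio of these pooled reads, each divided by the pooled TMM-scaled library sizes, is given with its 95% counting interval, and it differs from the ratio of the mean CPM printed beside it. These intervals and bounds cover counting error only, since reads without molecular identifiers are not independent molecules. Nothing in the labels says that libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

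The design, the comparisons, 23 gene lists, the rule for named genes and all alternatives but 1 were chosen before the data were examined. The lists covered chandelier cell genes, VIP and caudal ganglionic eminence (CGE) interneuron genes, SOM interneuron genes, medial ganglionic eminence (MGE) transcription factors, GABAergic neuron genes, axon initial segment and node genes, olfactomedin domain genes, synaptic organizers, immunoglobulin superfamily adhesion genes, cadherins and protocadherins, axon guidance genes, neuropeptides, voltage-gated potassium and pacemaker channels, GABA-A and glutamate receptor subunits and immediate early and dissociation stress genes. They also covered markers of excitatory neurons, the oligodendrocyte lineage, astrocytes, microglia and macrophages, endothelial and mural cells, erythrocytes, cell division and mitochondrially encoded mRNAs. Lists with at least 3 tested members, 19 of the 23, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Each list was tested again with an estimated correlation and with fry, and members were also adjusted over the list alone.

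Named genes were Nkx2-1, Sst, Vip, Gldn, Nfasc, Igsf11, Lhx6, Gad1 and Gad2 in every comparison. To these came the 8 genes per direction with the largest fitted fold among those past the threshold, with at least 10 CPM in the higher group and with no overlap between the libraries of the groups. For SOM against VIP, and for genes differing from both groups, the rule took 5 and 12 per direction. For each list it took up to 4 members past the threshold or, with none, the 2 most abundant members. Symbols of predicted genes were passed over, and 3 list members are not reported here by name, though they stayed in every test and count.

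Alternatives were DESeq2 size factors, no filter, a filter of at least 10 reads in at least 3 libraries, the DESeq2 1.42.0 Wald test, limma-voom with sample quality weights, robust empirical Bayes, only the libraries of the groups compared, the sample number as a block, a minimum log2 fold of 1, and leaving out each library in turn. The code was tested on simulated counts with the means and dispersions of these libraries, in which 50 genes were changed at each of 4 folds. For Nkx2.1 against SOM, with 10318 genes, 2% of genes changed by 4-fold, 10% by 16-fold, 24% by 64-fold and 44% by the largest fold simulated were recovered, with 2 false calls. For Nkx2.1 against VIP, with 10356 genes, the shares were 0%, 6%, 24% and 36%, with 1 false call. For SOM against VIP, with 10451 genes, they were 0%, 4%, 20% and 46%, with 0 false calls. Replicates were compared before averaging, and no pair of libraries of a group came within sampling noise (chi-square per degree of freedom 126 to 703).

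Gene positions came from the GENCODE M21 annotation of GRCm38, the assembly of mm10, with 1-based coordinates. Of the 23319 symbols, 21654 (92.9%) matched 1 gene there. Counts of protein-coding genes by strand left out clustered families and predicted genes named Gm with a number. Among these families were olfactory and vomeronasal receptors, keratins, histones and the clustered protocadherins.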

Results

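Gene expression was counted in 9 libraries, each of 150 hand-picked green fluorescent cells. These came from the upper layers of the medial prefrontal and anterior cingulate cortex of mice at postnatal day 5. Cells of 3 Nkx2.1 libraries came from Nkx2.1-CreER;Ai47 mice given tamoxifen on embryonic day 17, a scheme used to label chandelier cells, the interneurons that innervate the axon initial segment of pyramidal neurons. The other 6 libraries held 3 of cells from the somatostatin line (SOM-Cre;Ai47) and 3 from the vasoactive intestinal peptide line (VIP-Cre;Ai47). Reads in genes numbered 10850303, 12465997 and 11868308 in Nkx2.1 replicates 1 to 3, 9184008, 6484488 and 8580921 in the SOM replicates and 8071044, 8896919 and 11439809 in the VIP replicates. Genes with at least 1 read numbered 10576, 8180 and 9484 in the Nkx2.1 libraries, 10923, 11081 and 11490 in the SOM libraries and 9672, 10924 and 10927 in the VIP libraries. After thinning every library to 6484488 reads the Nkx2.1 libraries held 9090 ± 1184 genes, the SOM libraries 11070 ± 308 and the VIP libraries 10310 ± 695 (mean ± SD, n = 3). Across genes, which are not independent replicates, the correlation of log CPM was 0.461 to 0.484 between Nkx2.1 libraries, 0.616 to 0.666 between SOM libraries and 0.543 to 0.604 between VIP libraries. Between libraries of Nkx2.1 and SOM it was 0.439 to 0.533.

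**Figure D1:**
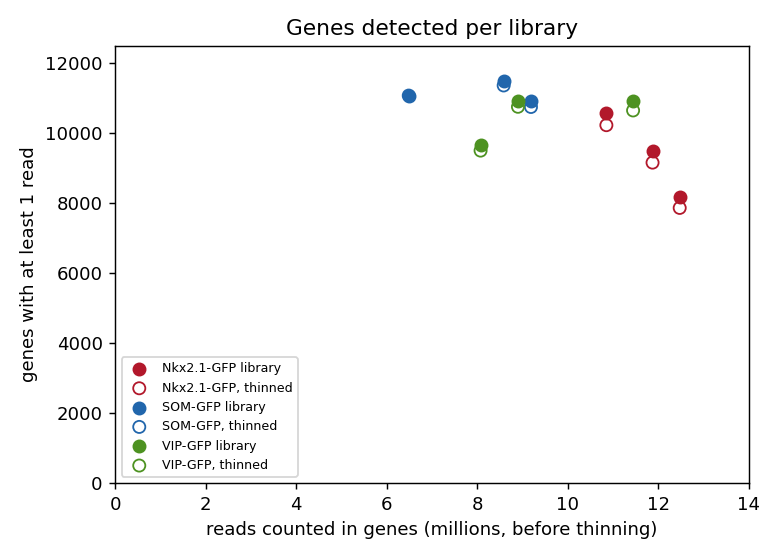
Genes with at least 1 read (vertical axis) against reads in genes (horizontal axis) for the 9 libraries, with filled points as counted and open points after thinning to 6484488 reads. Nkx2.1 replicates 2 and 3 held 8180 and 9484 genes, below the 9672 genes of VIP replicate 1, the lowest of the other 6 libraries.

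The genes behind the driver lines and the series title were read in each library. Sst (chromosome 16, 23889573 to 23890958, minus strand, GRCm38), which encodes somatostatin, stood at 1747 ± 382 CPM in SOM libraries, 17.7 ± 18.2 in Nkx2.1 libraries and 0.0412 ± 0.0714 in VIP libraries. Vip (chromosome 10, 5639218 to 5647617, plus strand) stood at 639 ± 203 CPM in VIP libraries, 1.18 ± 2.05 in Nkx2.1 libraries and 0.423 ± 0.732 in SOM libraries. Nkx2-1 (chromosome 12, 56531958 to 56536908, minus strand), the transcription factor of the MGE whose gene drives the third line, had 12, 10 and 1 reads in the Nkx2.1 libraries, 1 read in SOM replicate 3 and 0 in the other 5. Gldn (chromosome 9, 54286486 to 54341786, plus strand), which encodes gliomedin, had 1571 reads (180 CPM) in Nkx2.1 replicate 1 and 0 in Nkx2.1 replicates 2 and 3, which allows up to 0.256 and 0.25 CPM. Outside them it had 1 read, in SOM replicate 3. Neither Nkx2-1 nor Gldn met the filter, so neither was tested. Nfasc (chromosome 1, 132564690 to 132741797, minus strand), which encodes neurofascin, stood at 148 ± 143, 215 ± 15.98 and 237 ± 119 CPM in Nkx2.1, SOM and VIP libraries and was not called in any comparison. Its fold turned direction between Nkx2.1 and SOM without Nkx2.1 replicate 2 (log2 0.043) and between SOM and VIP without VIP replicate 1 (log2 0.36). Gad1 and Gad2, which encode the enzymes of GABA synthesis, stood at 1263 ± 545 and 352 ± 104 CPM in Nkx2.1 libraries, 1189 ± 164 and 576 ± 175 in SOM libraries and 1478 ± 497 and 312 ± 149 in VIP libraries, and neither was called in any comparison.

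**Figure D2:**
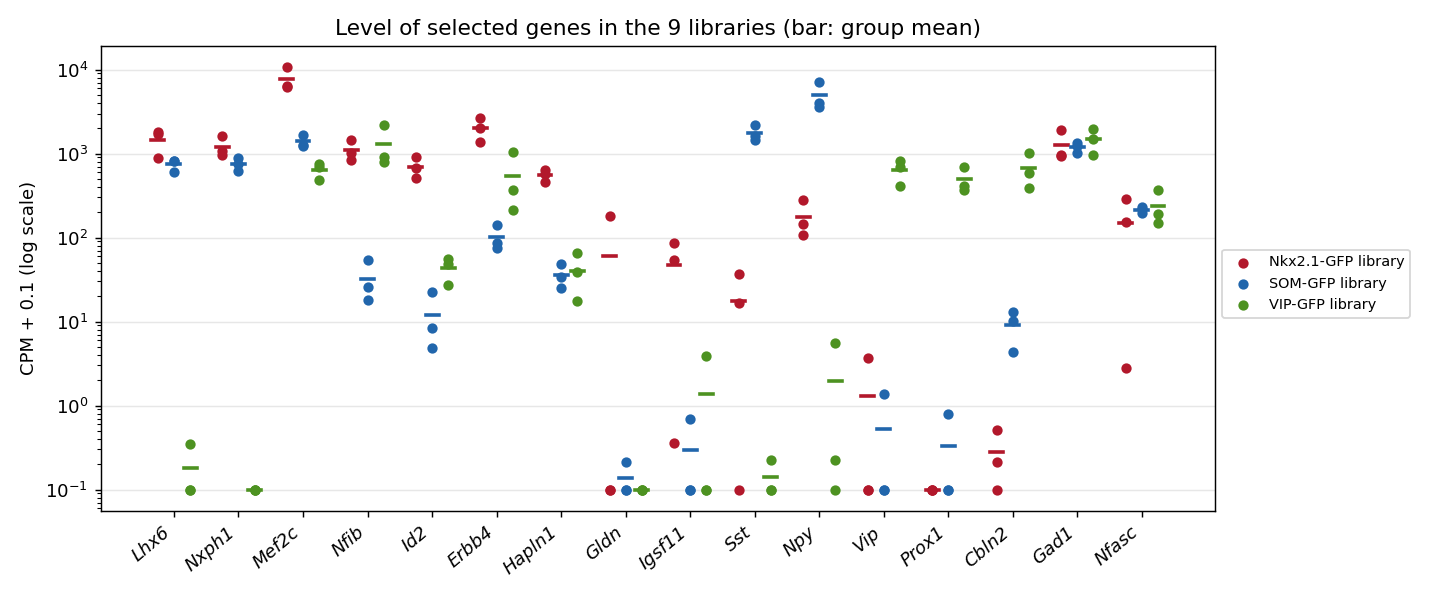
CPM plus 0.1 on a log axis for 16 genes in the 9 libraries, with points for libraries, colours for the groups and bars for group means. Lhx6 and Nxph1 stood at 608 CPM or more in every Nkx2.1 and SOM library and at 0.247 CPM or less in every VIP library, while Gldn had more than 1 read in Nkx2.1 replicate 1 alone.

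The comparison of Nkx2.1 with SOM cells sets the line used to label chandelier cells beside a line for another interneuron type of MGE origin. In the Nkx2.1 libraries 7 transcripts were higher, among them transcription factors and a receptor of interneuron development. Id2, an inhibitor of basic helix-loop-helix factors, rose 59.7-fold (700 ± 198 against 11.7 ± 9.19 CPM; log2 5.90 ± 0.76 SE, edgeR adjusted p = 0.024). Nfib, a nuclear factor I transcription factor, rose 34.2-fold (1110 ± 316 against 32.5 ± 18.6 CPM; log2 5.09 ± 0.59, edgeR adjusted p = 0.0144). Erbb4 (chromosome 1, 68032186 to 69108059, minus strand), the neuregulin receptor, rose 19.9-fold (2008 ± 636 against 101 ± 35.7 CPM; log2 4.31 ± 0.62, edgeR adjusted p = 0.0458). Mef2c (chromosome 13, 83504034 to 83667080, plus strand), an activity-regulated transcription factor, rose 5.57-fold (7751 ± 2574 against 1393 ± 240 CPM; log2 2.48 ± 0.27, edgeR adjusted p = 0.0144). The noncoding RNA Malat1 rose 4.66-fold, the basic helix-loop-helix factor Tcf4 3.15-fold and Nrep 3.13-fold (edgeR adjusted p = 0.0473, 0.0133 and 0.0154). Lower were 3 transcripts: the ribosomal RNA precursor Rn45s 11.9-fold, the growth cone gene Gap43 3.97-fold (582 ± 131 against 2311 ± 179 CPM) and Fxyd6, a regulator of the sodium pump, 3.26-fold (319.9 ± 25.5 against 1044 ± 162 CPM), with edgeR adjusted p = 0.0144, 0.036 and 0.0473. Of these genes, Nfib, Tcf4 and Gap43 were also called in SOM against VIP, with SOM the group apart in both comparisons. None of them was called in Nkx2.1 against VIP (DESeq2 log2 -0.20, 0.48 and -0.011). In all 10 genes every library of one group lay above every library of the other, as did 2138 of the 10728 genes tested (19.9%, against 10% by chance). Sst and Npy, at 177 ± 88.5 against 4918 ± 1986 CPM for Npy, also had no overlap between the groups but were not called (log2 -6.63 and -4.80, edgeR adjusted p = 0.288 and 0.309). Lhx6, a transcription factor of MGE interneurons, stood at 1455 ± 493 against 745 ± 119 CPM (edgeR adjusted p = 0.642), and Igsf11, a synaptic adhesion gene, at 46.8 ± 43.3 against 0.199 ± 0.344 CPM (edgeR adjusted p = 0.436). At an unadjusted p under 0.05 there were 313 genes higher and 899 lower, and the DESeq2 Wald test called 199 higher and 743 lower. DESeq2 also called 194 to 401 genes in splits that mix these 2 groups. At 1 depth the Nkx2.1 libraries held fewer genes (9090 ± 1184 against 11070 ± 308), and only they had tamoxifen. The line, tamoxifen and a loss of transcripts cannot be told apart as sources of the excess of lower genes. The higher genes numbered 3, 0 and 4 without SOM replicates 1, 2 and 3 and 3 without Nkx2.1 replicate 2; the lower ones 1 without VIP replicate 1, 0, 0 and 1 without SOM replicates 1, 2 and 3, and 29, 1 and 5 without Nkx2.1 replicates 1, 2 and 3. None of the 10 calls was kept without SOM replicate 2, where the lowest adjusted p among them was 0.103.

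**Figure D3:**
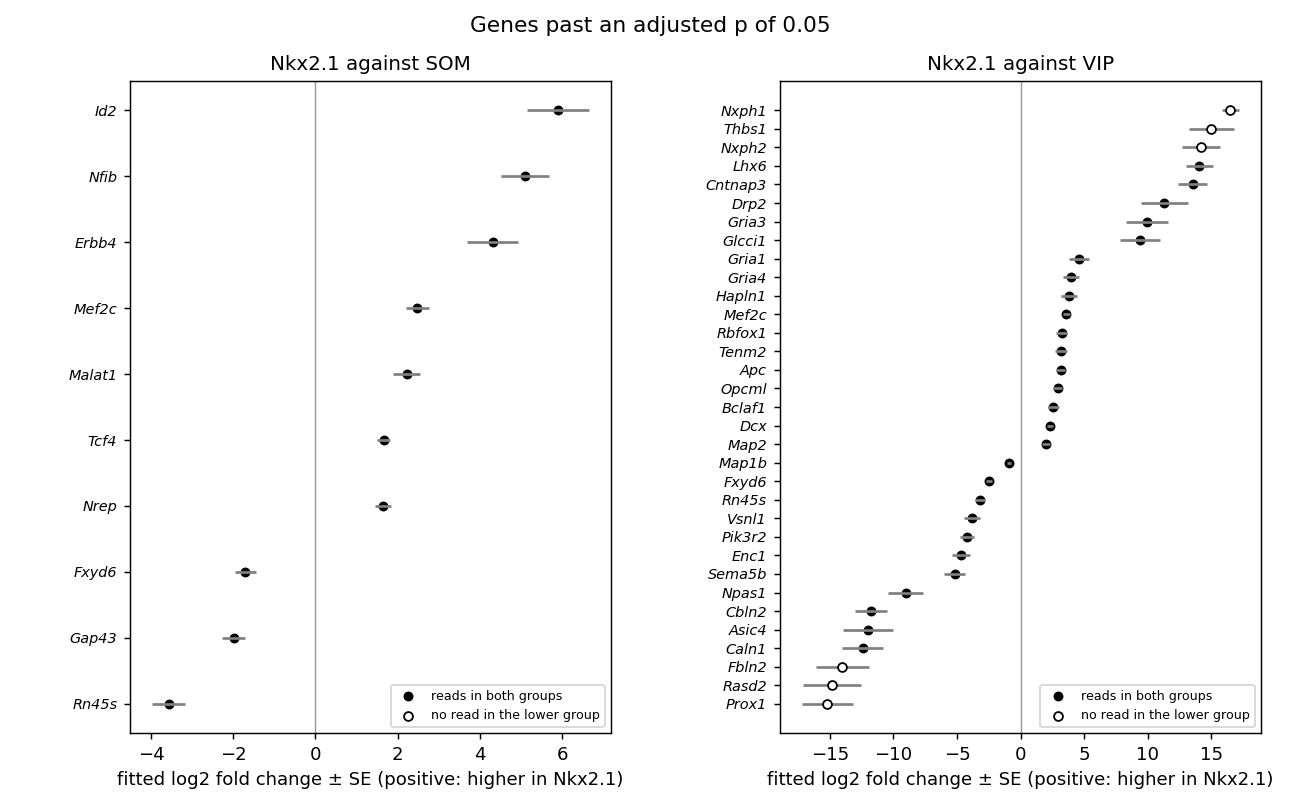
Fitted log2 fold change ± SE (horizontal axis) of the genes past an edgeR adjusted p of 0.05 in Nkx2.1 against SOM (left, 10 genes) and Nkx2.1 against VIP (right, 33 genes), with positive values higher in Nkx2.1. Open points mark genes without a read in the lower group, whose fitted value depends on the prior count and is no estimate of the fold. Their SE was computed from that value and has the same limit.

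Members named beside a count of 5 or fewer were chosen after their values were seen, unless the rule for named genes took them. Among the lists, chandelier cell genes were higher in Nkx2.1 than in SOM libraries, with 1 of the 8 tested members called (Erbb4). The call of Erbb4 was lost in 6 of the 9 fits that left out 1 library. Adjusted over the list alone 4 were higher, among them Erbb4, Hapln1 and Fgf13, and 0 lower. The camera test gave an adjusted p = 3.58e-08, and adjusted p = 0.143 with an estimated correlation. SOM interneuron genes were lower, with 0 of 12 called and 8 lower adjusted over the list alone. Its most abundant members were the neuropeptide gene Npy and the extracellular matrix gene Reln, the latter at 346 ± 594 against 2455 ± 360 CPM. That list had a camera adjusted p = 1.97e-07, and adjusted p = 0.268 with an estimated correlation. VIP and CGE interneuron genes were also lower (0 of 13 called, 5 lower adjusted over the list alone; camera adjusted p = 0.00344, and adjusted p = 0.593 with an estimated correlation). The named members Synpr and Cnr1 stood at 6.94 ± 12.02 against 810 ± 396 CPM and 303 ± 214 against 394 ± 180 CPM. The list call had an adjusted p = 0.061 without SOM replicate 1 and 0.0877 without Nkx2.1 replicate 3. Astrocyte markers had 0 of 8 called, 0 adjusted over the list alone and a camera adjusted p = 0.0381 in the direction of Nkx2.1, and adjusted p = 0.689 with an estimated correlation. Without Nkx2.1 replicate 1 and without SOM replicate 3 it was 0.722 and 0.0677. Their summed level was 3690, 668 and 312 CPM in the Nkx2.1 libraries and 79.5 to 240 CPM in the SOM libraries. The other 15 tested lists were not called (camera adjusted p = 0.0927 to 0.871). Olfactomedin domain genes, the family of gliomedin, were nearest, with 0 of 6 called and 1 lower adjusted over the list alone (Olfm3, 38.7 ± 41.0 against 795 ± 172 CPM). Axon initial segment and node genes (camera adjusted p = 0.404) had 0 of 19 called and 2 higher (Scn1a and Fgf13) and 1 lower (L1cam) adjusted over the list alone. For MGE transcription factors, GABAergic neuron genes, axon initial segment genes, immediate early genes, excitatory neuron markers, synaptic organizers, immunoglobulin superfamily adhesion genes and neuropeptides the median, the mean and the test did not share 1 sign here.

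The comparison of Nkx2.1 with VIP cells sets a line for interneurons of MGE origin beside a line for interneurons of CGE origin. Here 19 genes were higher in Nkx2.1 and 14 lower. Nxph1 (chromosome 6, 8948431 to 9249032, plus strand), a secreted ligand of neurexins, stood at 1208 ± 343 CPM against 0 reads in the VIP libraries and was at least 12300-fold higher (edgeR adjusted p = 7.29e-05). Lhx6 (chromosome 2, 36081953 to 36105408, minus strand) stood at 1455 ± 493 against 0.0824 ± 0.143 CPM (ratio of pooled reads 22500, counting interval 6230 to 186000; edgeR adjusted p = 0.000438). Mef2c rose 12.1-fold (log2 3.59 ± 0.29, edgeR adjusted p = 0.000532) and the contactin-associated gene Cntnap3 stood at 575 ± 261 against 0.0412 ± 0.0714 CPM (ratio of pooled reads 16900, 3020 to 666000; edgeR adjusted p = 0.000628). Nxph2 and Thbs1, a thrombospondin, were at least 2460-fold and 4200-fold higher (edgeR adjusted p = 0.0098 and 0.0171). The AMPA receptor subunit genes Gria1 and Gria4 rose 24.4-fold and 15.7-fold, and Gria3 stood at 114 ± 113 against 0.104 ± 0.180 CPM (edgeR adjusted p = 0.0486, 0.0376 and 0.0436). The adhesion genes Opcml and Tenm2 and the perineuronal matrix gene Hapln1 rose 7.64-fold, 8.95-fold and 13.8-fold (edgeR adjusted p = 0.0098, 0.0295 and 0.0474), and Drp2 and Glcci1 2990-fold and 718-fold (0.0436 for both).

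On the lower side of the same comparison, Prox1 (chromosome 1, 190118035 to 190170714, minus strand), a transcription factor of CGE interneurons, had 0 reads in the Nkx2.1 libraries against 492 ± 177 CPM and was at least 5580-fold lower (edgeR adjusted p = 0.0316). Npas1, a transcription factor of interneurons, was 532-fold lower (1.03 ± 1.09 against 547 ± 55.4 CPM, edgeR adjusted p = 0.0325). Cbln2, a secreted synaptic organizer, was 3750-fold lower and Asic4, of the acid-sensing channel family, 3940-fold lower (edgeR adjusted p = 0.0045 and 0.0436). Fxyd6 (chromosome 9, 45370185 to 45396159, plus strand) was 5.56-fold lower (log2 -2.47 ± 0.26, edgeR adjusted p = 0.00361) and Rn45s 9.08-fold lower (0.0098). Rasd2 and Fbln2 were at least 3960-fold and 2190-fold lower, the calcium-binding gene Caln1 stood at 0.0381 ± 0.0660 against 256.2 ± 80.3 CPM (ratio of pooled reads 8130, 1460 to 321000), and the semaphorin Sema5b was 36.2-fold lower (edgeR adjusted p = 0.0486, 0.0474, 0.0127 and 0.0411). Vip, 1.18 ± 2.05 against 639 ± 203 CPM, was not called (log2 -9.10 ± 2.26, edgeR adjusted p = 0.148), nor were Sst (0.133), Igsf11 (0.488) and Nfasc (0.863). All 33 called genes had no overlap between the groups, as did 2160 genes (20.1%, against 10% by chance). An unadjusted p under 0.05 was found for 615 higher and 1012 lower genes, and DESeq2 called 463 higher and 914 lower. DESeq2 called 390 to 724 genes in splits that mix these groups. At 1 depth the Nkx2.1 libraries held 9090 ± 1184 genes and the VIP libraries 10310 ± 695, with overlap. The line, tamoxifen and a loss of transcripts cannot be told apart as sources of the excess of lower genes.

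Leaving out libraries moved both counts of Nkx2.1 against VIP. The higher genes numbered 11 and 9 without VIP replicates 1 and 3, 12 without SOM replicate 2 or 3 and 12 without Nkx2.1 replicate 1. The lower genes numbered 5, 5 and 3 without VIP replicates 1, 2 and 3, 9 and 7 without SOM replicates 2 and 3, and 36, 9 and 27 without Nkx2.1 replicates 1, 2 and 3. Of the 33 calls 10 were kept whichever library was left out: Lhx6, Nxph1, Nxph2, Cntnap3, Mef2c, Apc and Dcx among the higher genes and Cbln2, Fxyd6 and Rn45s among the lower ones. Apc and Dcx, of the neuronal cytoskeleton, lie outside the rule for named genes and were named after their values were seen (8.88-fold and 4.92-fold higher, edgeR adjusted p = 0.00923 and 0.00305).

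In the lists, VIP and CGE interneuron genes were lower in Nkx2.1 than in VIP libraries, with 2 of 13 tested members called (Prox1 and Npas1) and 12 lower adjusted over the list alone (camera adjusted p = 2.63e-20, and adjusted p = 0.0239 with an estimated correlation). These transcription factors were at 0 and 1.03 ± 1.09 CPM in Nkx2.1 libraries. Cck and Htr3a of this list had 0 reads in all 9 libraries and were named after their values were seen. Both lie in a stretch of chromosome 9 where none of the 426 minus-strand protein-coding genes counted had a read. MGE transcription factors were higher, with 2 of 6 called (Lhx6 and Mef2c), also adjusted over the list alone (camera adjusted p = 1.98e-07, and adjusted p = 0.0442 with an estimated correlation). Chandelier cell genes were higher, with 1 of 8 called (Hapln1) and 2 adjusted over the list alone (Hapln1 and Erbb4). That list had a camera adjusted p = 0.00111, and adjusted p = 0.144 with an estimated correlation. The call of Hapln1 was lost in all 9 fits that left out 1 library. Axon initial segment and node genes were higher as a list, with 0 of 19 called and 0 adjusted over the list alone (camera adjusted p = 0.0107, and adjusted p = 0.112 with an estimated correlation). Its most abundant members, the adhesion gene Chl1 and the scaffold gene Ank3, stood at 1788 ± 442 against 884 ± 259 CPM and 1277 ± 290 against 523 ± 365 CPM. Cadherins and protocadherins were higher (0 of 22 called, 1 adjusted over the list alone; camera adjusted p = 0.0232, and adjusted p = 0.112 with an estimated correlation), with Cdh13 at 307 ± 119 against 35.4 ± 29.9 CPM. Without Nkx2.1 replicate 1 that p was 0.0961. Axon guidance genes (0 of 36 called, 2 higher adjusted over the list alone) and immediate early and dissociation stress genes (0 of 11, 0 adjusted over the list alone) had camera adjusted p = 0.0439 each in the direction of Nkx2.1, and adjusted p = 0.44 each with an estimated correlation. For axon guidance it was 0.0538 without VIP replicate 1 and 0.313 and 0.0705 without Nkx2.1 replicates 1 and 3. For immediate early genes it was 0.172 without VIP replicate 2 and 0.0706 and 0.183 without Nkx2.1 replicates 2 and 3. The immediate early gene Fos stood at 852 ± 324 against 167 ± 155 CPM. GABA-A and glutamate receptor subunits had 3 of 26 called (Gria1, Gria3 and Gria4), 6 higher and 3 lower adjusted over the list alone, and no list call (camera adjusted p = 0.0908). For that list it was 0.0443 without VIP replicate 3. The other 11 tested lists had camera adjusted p = 0.0683 to 0.825. SOM interneuron genes (0.0683) had 0 of 12 called, 5 higher and 1 lower adjusted over the list alone, and p of 0.000815 and 0.0426 without VIP replicates 2 and 3, 0.0429 and 0.0373 without SOM replicates 2 and 3, and 0.00577 and 0.0215 without Nkx2.1 replicates 2 and 3. Astrocyte markers (0.311) had 0.0202 without Nkx2.1 replicate 3. Among the 11, synaptic organizers had 1 of 33 higher (Tenm2) and 1 lower (Cbln2), and 1 higher and 3 lower adjusted over the list alone. Immunoglobulin superfamily adhesion genes had 1 of 27 higher (Opcml), and 4 higher and 3 lower adjusted over the list alone. The median, mean and test did not share 1 sign for GABAergic neuron genes and excitatory neuron markers.

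The comparison of SOM with VIP cells served as a reference between the other lines. Nxph1 stood at 757.5 ± 136 CPM against 0 reads in VIP libraries and was at least 7670-fold higher in SOM (edgeR adjusted p = 9.26e-05). Lhx6 stood at 745 ± 119 against 0.0824 ± 0.143 CPM (ratio of pooled reads 11000, 3030 to 90500; edgeR adjusted p = 0.000685) and Cntnap3 at 203 ± 43.3 against 0.0412 ± 0.0714 CPM (ratio of pooled reads 5940, 1070 to 235000; edgeR adjusted p = 0.00177). Nxph2 and Thbs1 were at least 858-fold and 2170-fold higher (edgeR adjusted p = 0.0334 and 0.0451), and Gap43 was 3.90-fold higher (0.04; named after its values were seen). On the lower side, Nfib was 39.7-fold lower (32.5 ± 18.6 against 1289 ± 761 CPM; log2 -5.31 ± 0.60, edgeR adjusted p = 0.0108) and Tcf4 2.31-fold lower (edgeR adjusted p = 0.0353). Sst, with 42265 reads in the SOM and 1 in the VIP libraries (ratio of pooled reads 50900, 9140 to 2010000), was not called (edgeR adjusted p = 0.0534). Npy, 4918 ± 1986 against 1.88 ± 3.15 CPM, and Vip, 0.423 ± 0.732 against 639 ± 203 CPM, were not called either (edgeR adjusted p = 0.0582 and 0.296). The 8 called genes, 6 higher and 2 lower, had no overlap between the groups, as did 2130 genes (19.9%, against 10% by chance). At an unadjusted p under 0.05 there were 497 higher and 253 lower, and DESeq2 called 329 and 171. The higher genes numbered 3 without SOM replicate 2 or 3 and 3 without Nkx2.1 replicate 3; the lower ones 1 without VIP replicate 2 or 3, 0 without SOM replicate 2 or 3, and 5, 8 and 1 without Nkx2.1 replicates 1, 2 and 3. Lhx6, Nxph1 and Cntnap3 were kept whichever library was left out.

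Of the lists in SOM against VIP, VIP and CGE interneuron genes were lower (0 of 13 called, 9 lower adjusted over the list alone; camera adjusted p = 1.75e-19, and adjusted p = 0.0347 with an estimated correlation), with Synpr at 810 ± 396 against 2305 ± 286 CPM and the cannabinoid receptor gene Cnr1 at 394 ± 180 against 2115 ± 672 CPM. SOM interneuron genes were higher (0 of 12 called, 6 adjusted over the list alone; camera adjusted p = 3.25e-15, and adjusted p = 0.0631 with an estimated correlation), with the extracellular matrix gene Reln at 2455 ± 360 against 13.5 ± 21.01 CPM. MGE transcription factors were higher, with 1 of 6 called (Lhx6) and 2 adjusted over the list alone (Lhx6 and Mef2c; camera adjusted p = 1.11e-09, and adjusted p = 0.0299 with an estimated correlation). Cadherins and protocadherins were higher (0 of 22 called, 2 adjusted over the list alone, Cdh9 and Cdh13; camera adjusted p = 0.00252, and adjusted p = 0.0843 with an estimated correlation). GABA-A and glutamate receptor subunits were higher as a list, with 0 of 26 called, and 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0129, and adjusted p = 0.266 with an estimated correlation; 0.0528 without SOM replicate 1). Gria1 stood at 1663 ± 370 against 99.7 ± 116 CPM. The other 14 tested lists were not called (camera adjusted p = 0.0578 to 0.88), but leaving out 1 library brought some past the threshold. Chandelier cell genes (0.0578) had 0 of 8 called and 1 lower adjusted over the list alone, and p of 0.00385 and 0.0446 without VIP replicates 1 and 2, 0.0252 and 0.0481 without SOM replicates 2 and 3, and 0.0456 without Nkx2.1 replicate 3. Axon initial segment and node genes (0.0584) had 0.045 without SOM replicate 2 and 0.0493 without Nkx2.1 replicate 2. Synaptic organizers (0.0578) had 0.0439 without Nkx2.1 replicate 3, and immediate early genes (0.15) had 0.0178 without SOM replicate 3. The median, mean and test did not share 1 sign for astrocyte and excitatory neuron markers.

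Genes that set the Nkx2.1 libraries apart from both other groups were 3. Mef2c was higher than in both, at 7751 ± 2574 CPM against 1393 ± 240 in SOM and 643 ± 143 in VIP libraries. Fxyd6 was lower than in both, at 319.9 ± 25.5 CPM against 1044 ± 162 and 1778 ± 270, and Rn45s was lower at 165 ± 40.3 CPM against 1961 ± 881 and 1498 ± 241. Against SOM, leaving out 1 library in turn lost the call of Fxyd6 in 8 of the 9 fits, of Rn45s in 3 and of Mef2c in 2. Against VIP all 3 were kept whichever library was left out. No gene was called in opposite directions. Both comparisons share the Nkx2.1 libraries. Independent lists of these sizes would share 0.0124 higher and 0.00391 lower genes, and 20 simulations of unchanged groups gave 0 and 0. The correlation of the fold changes over 10728 genes was 0.68, against 0.495 (0.476 to 0.519) in the simulations, and the covariance 6.5 against 2.3, a difference of 4.19. The 3 Nkx2.1 libraries cannot be split into parts of 2, so part of the excess may come from the shared libraries. The simulations also gave all groups the same dispersion per gene. The Nkx2.1 libraries correlated at 0.461 to 0.484 with each other, the SOM libraries at 0.616 to 0.666. A wider spread in the shared group raises both measures, so no conclusion is drawn from the excess over these simulations. Without 1 library the higher count was 2 (VIP replicate 1 or SOM replicate 3) or 0 (SOM replicate 1 or 2), and DESeq2 gave 67. The lower count was 1 without any 1 VIP library or SOM replicate 3, 0 without SOM replicate 1 or 2, 25, 0 and 5 without Nkx2.1 replicates 1, 2 and 3, and 520 with DESeq2.

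Markers of other cell types were read in all groups. Slc1a3 and Fabp7, of astrocytes and radial glia, stood at 1662 and 1249 CPM in Nkx2.1 replicate 1, 295 and 329 in replicate 2 and 4.93 and 84.6 in replicate 3. In SOM libraries they stood at 20.98 ± 14.8 and 53.0 ± 38.1 CPM and in VIP libraries at 21.9 ± 36.2 and 57.8 ± 46.0 CPM. Oligodendrocyte lineage markers had 0 of 6 tested members called in each comparison (camera adjusted p = 0.74, 0.0683 and 0.0578 for Nkx2.1 against SOM, Nkx2.1 against VIP and SOM against VIP). Their p in Nkx2.1 against VIP was 0.0436, 0.00911 and 0.0206 without VIP replicates 1, 2 and 3, 0.018, 0.0104 and 0.0114 without SOM replicates 1, 2 and 3, and 0.000899 without Nkx2.1 replicate 2. In SOM against VIP it was 0.0406 without VIP replicate 2, 0.0073 without SOM replicate 3, and 0.0417 and 0.0439 without Nkx2.1 replicates 2 and 3. In Nkx2.1 against SOM it was 0.049 without Nkx2.1 replicate 2. Cell division genes had 0 of 3 called in each (0.871, 0.422 and 0.374), and excitatory neuron markers 0 of 7 (0.871, 0.599 and 0.88). GABAergic neuron genes had 0 of 10 called in each (0.871, 0.787 and 0.374). Voltage-gated potassium and pacemaker channels had 0 of 18 called in each (0.844, 0.825 and 0.68) and neuropeptide genes 0 of 9 (0.496, 0.443 and 0.374). Adjusted over the list alone, neuropeptide genes had 0 higher and 4 lower, 3 higher and 3 lower, and 2 higher and 4 lower in these comparisons. The list had a camera adjusted p = 0.0214 in Nkx2.1 against SOM without Nkx2.1 replicate 1. Microglia and macrophage markers, with 2 tested members, were too few for a list test. P2ry12, a purinergic receptor gene of microglia, stood at 0.114 ± 0.198, 8.42 ± 9.04 and 5.72 ± 4.96 CPM in Nkx2.1, SOM and VIP libraries. Endothelial and mural cell markers summed to at most 17.6 CPM in any library, with 0 members tested. Of the erythrocyte genes 3 had an entry, with Hba-a1 at 0 reads in all 9 libraries and Alas2 at no more than 7.35 CPM in any. Mitochondrially encoded mRNAs were not analysed here.

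Reads were missing from long runs of neighbouring genes on single strands in all 9 libraries. On the minus strand of chromosome 9, none of the 426 protein-coding genes from position 21294275 to 124476898 had a read, while 353 of 442 genes (79.9%) of the plus strand there had at least 1. On the minus strand of chromosome 19 the same held for 121 genes from 27761721 to 60581025, with reads in 106 of 139 genes (76.3%) of the plus strand. Over the genome 12464 of the 16963 protein-coding genes counted (73.5%) had a read. Clustered families such as olfactory receptors, and predicted Gm genes, were left out of all these counts and shares. The cell cycle inhibitor gene Cdkn2d (chromosome 9, 21288410 to 21291407, minus strand), next to the first run, took 2.90% to 3.29% of the gene reads of each library. Gldn and Fxyd6 lie on the plus strand of chromosome 9. Ncam1, a neural cell adhesion gene, and Cx3cr1, a microglial gene, lie in the first run.

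**Figure D4:**
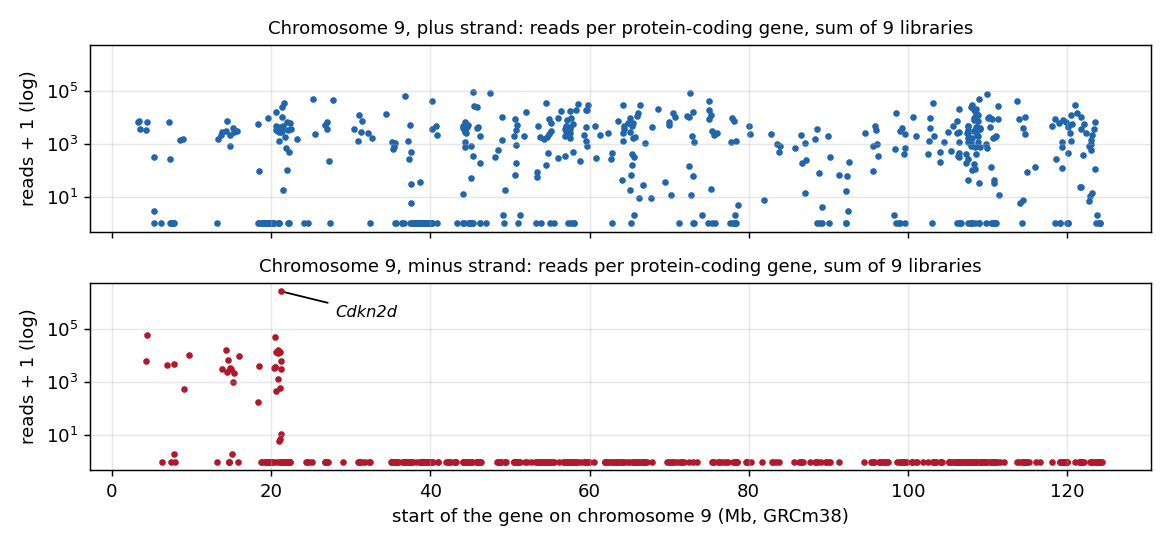
Reads plus 1 per protein-coding gene, summed over the 9 libraries on a log axis, against the start of the gene on chromosome 9 (Mb, GRCm38), for the plus strand (top) and the minus strand (bottom), with 1 point per gene. The points include the clustered families and predicted genes that the counts leave out. Of the genes counted from 21294275 to 124476898, all 426 of the minus strand sit at 0 reads. On the plus strand 353 of the 442 genes counted have reads.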

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

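The alternatives were planned except 1, chosen after seeing the data, which left out the genes of the strand runs without reads, and which gave 7, 3, 19, 14, 6, 3, 1 and 2 genes. These counts, and those below, are in the order Nkx2.1 against SOM higher and lower, Nkx2.1 against VIP higher and lower, SOM against VIP higher and lower, and both higher and lower, where the edgeR test gave 7, 3, 19, 14, 6, 2, 1 and 2. A filter of at least 10 reads in at least 3 libraries gave these 8 counts too, and robust empirical Bayes 8, 3, 18, 12, 6, 3, 1 and 2. A minimum log2 fold of 1 gave 7, 3, 19, 13, 6, 2, 1 and 2. With DESeq2 size factors the genes lower than both numbered 1, so that 50% of the genes apart from both were higher. Without a filter SOM against VIP gave 14 and 7 genes and both gave 4 and 1. The DESeq2 Wald test gave 199, 743, 463, 914, 329, 171, 67 and 520 genes, among them 10 of the 10, 32 of the 33 and 8 of the 8 genes called by edgeR. With limma-voom and sample quality weights Nkx2.1 against VIP had 1 lower gene, SOM against VIP 170 and 139, and both 3 and 0, and 5 of 10, 11 of 33 and 7 of 8 calls were kept. Mef2c was no longer called in either Nkx2.1 comparison there, so the 3 genes higher than both were other genes. Its median log2 fold of all genes was -0.97, -0.65 and 0.17, and its weights of the Nkx2.1 libraries were 0.599, 0.375 and 0.595, against 2.74 for SOM replicate 2. Only the libraries of the groups compared gave 4, 1, 10, 10, 14, 18, 0 and 0 genes. Leaving out 1 library gave ranges of 0 to 8, 0 to 29, 9 to 18, 3 to 36, 3 to 9, 0 to 8, 0 to 2 and 0 to 25 genes. For these moves the cause was not tested.

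The block on the sample number gave 3, 1, 8, 3, 3, 1, 1 and 1 genes, although the numbers did not pair the libraries: deviations from the group mean correlated at -0.0412 to 0.0671 between libraries with the same number and at -0.0708 to 0.0623 between others. With the block the log2 fold turned for Cux2 (-0.0084, Nkx2.1 against SOM) and, in SOM against VIP, for Nfasc (0.063), Igsf11 (0.18), Slc1a3 (1.22), P2ry12 (-1.29) and Ccna2 (0.038). With the block the camera adjusted p of astrocyte markers in Nkx2.1 against SOM was 0.077, no longer past the threshold, and that of oligodendrocyte lineage markers in Nkx2.1 against VIP 0.0454, now past it. The cause was not tested.

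With fry, which tests whether a list moves on balance one way and does not compare it with other genes, 6 called lists were past the threshold no longer: VIP and CGE interneuron genes (0.0693) and astrocyte markers (0.601) in Nkx2.1 against SOM, cadherins (0.0733), axon guidance (0.46) and immediate early genes (0.226) in Nkx2.1 against VIP, and GABA-A and glutamate receptor subunits (0.0968) in SOM against VIP. Lists past it with fry alone were potassium and pacemaker channels in Nkx2.1 against SOM (0.0347), synaptic organizers in Nkx2.1 against VIP (0.0407) and axon initial segment genes in SOM against VIP (0.0267).

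Of the 157 gene results followed, 10 turned direction with limma-voom, none of them called: Gad1 (-0.082), Nrxn3 (-0.029), Cux2 (-0.71) and Cnp (-2.50) in Nkx2.1 against SOM, Robo2 (-0.18), Neurod6 (4.97) and Mbp (-1.25) in Nkx2.1 against VIP, and Nfasc (0.19), Slc1a3 (2.12) and P2ry12 (-1.07) in SOM against VIP. Leaving out 1 library turned uncalled genes with these ranges of log2 fold. In Nkx2.1 against SOM they were Vip -5.13 to 6.52, Nfasc -1.45 to 0.043, Gad1 -0.32 to 0.27, Cnr1 -0.85 to 0.11, Chl1 -0.31 to 0.057, Lphn3 -0.67 to 0.31, Nrxn3 -0.070 to 0.24, Pcdh9 -0.29 to 0.49, Kcnd2 -0.065 to 0.79, Cux2 -0.55 to 0.66, Cnp -2.27 to 1.28 and Mbp -3.445 to 0.20. In Nkx2.1 against VIP they were Gad1 -0.64 to 0.081, Gad2 -0.10 to 0.67, Reln -2.12 to 7.935, Robo2 -0.43 to 0.42, Kcnip1 -0.33 to 0.079, Neurod6 -0.63 to 9.54 and Mbp -2.60 to 1.255. In SOM against VIP they were Nfasc -0.37 to 0.36, Igsf11 -6.69 to 3.95, Ank3 -0.14 to 0.87, Neurod6 -11.83 to 2.83, Mbp -0.065 to 1.97, Slc1a3 -0.81 to 4.43, Fabp7 -0.89 to 0.79, P2ry12 -0.65 to 1.14, Ccna2 -0.38 to 0.31 and Nr4a1 -0.31 to 1.255. The cause was not tested.

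For each pair of groups the 10 splits of the 6 libraries are too few for a share under 0.05. The real split gave 7 and 3, 19 and 14, and 6 and 2 genes, each count reached in 1 split, with a highest other of 0 by edgeR. The lists past the threshold numbered 4 in Nkx2.1 against SOM (reached in 2 splits, highest other 4), 7 in Nkx2.1 against VIP (1 split, highest other 5) and 5 in SOM against VIP (1 split, highest other 3). DESeq2 called 942, 1377 and 500 genes in the real splits and 194 to 401, 390 to 724 and 58 to 129 in the others. The 9 libraries were also split in 100 ways, of which 1 was the real split and the rest were drawn. Only the real split gave as many genes higher than both as the real count of 1 (highest other 0). As many lower genes as the real 2 came from 4 splits, the real split among them (highest other 5). All splits but the real ones mix the lines within a group, which widens its spread. Both real counts of genes apart from both groups were 0 without SOM replicate 1 or 2, so chance was not excluded by the splits.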

Other observations

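The test of random loss and that of random jumps were chosen before their results were seen, and the tests of strand counting, silent stretches and whole astrocytes only after.

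Sodium channel genes of the axon initial segment were high in the Nkx2.1 libraries, and were chosen after their values were seen. Scn1a stood at 701.5 ± 109 CPM in Nkx2.1, 95.6 ± 84.9 in SOM and 85.4 ± 79.2 in VIP libraries, and was not called against either (edgeR adjusted p = 0.317 and 0.179). Scn8a stood at 212.5 ± 95.2, 63.3 ± 40.3 and 78.6 ± 44.2 CPM and was not called (edgeR adjusted p = 0.5 and 0.508). Fgf13, which encodes a partner of sodium channels, stood at 693 ± 82.6, 198 ± 39.8 and 390 ± 192 CPM (edgeR adjusted p = 0.287 and 0.392).

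Minus-strand genes of a stretch of chromosome 9 had no read in any library, and those of a stretch of chromosome 19 likewise. Silence or lack of these stretches is argued against by reads in 79.9% and 76.3% of the plus-strand genes there. A candidate explanation is that counting by strand lost these genes. A further candidate is that reads of the silent strand that hit no other gene were assigned to a neighbour. Cdkn2d held reads equal to 2.55% to 2.99% of those outside genes, where the stretch is 1.9% of both strands. Snora19 held 0.483% to 0.793%, where its stretch is 0.603%. Where the reads of the lost genes themselves went was not tested. On chromosome X, 55 plus-strand and 52 minus-strand genes had no read and the other strand had 0% with reads. That argues against loss by strand there, while silence or lack cannot be told apart from other losses without reads on either strand. The stretch holds Syp and Syn1, synaptic vesicle genes of neurons, named after their values were seen, so its zeros need not mean silence. No biological explanation was tested.

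Genes of glia and cell division were high in Nkx2.1 replicate 1, with Aqp4 at 183, Aldoc at 189 and Mki67 at 181 CPM there and at 0 in Nkx2.1 replicates 2 and 3, while VIP replicate 1 held Mki67 at 89 CPM and cell division genes at a sum of 164 CPM, against 476 CPM in Nkx2.1 replicate 1. Independent random jumps of single genes are argued against, since 67.7% of 31 members were highest in an Nkx2.1 library, against 19.4% to 51.6% in 10000 matched lists. A rise shared by the members in 1 library gives this result too. In Nkx2.1 replicate 1, 7 oligodendrocyte lineage and 5 cell division members lay above every SOM and VIP library. In replicate 2 these were 1 and 1, and in replicate 3 they were 3 and 0. Whole astrocytes among the picked cells cannot be told apart from other sources: 8 of the 12 astrocyte members lay above every SOM and VIP library in Nkx2.1 replicate 1, between the bounds set for and against, but 3 and 2 in replicates 2 and 3, where 3, 3 and 1 lay above every library of the other groups in VIP replicates 1, 2 and 3. The 12 members summed to 3690, 668 and 312 CPM in the Nkx2.1 and 532, 477 and 309 CPM in the VIP libraries; Slc1a3 and Fabp7, the most abundant, stood at 1662 and 1249 CPM in Nkx2.1 replicate 1, while Gja1 and Apoe stood at 1.14 and 27.3 CPM, and picking of fluorescent cells would remove unlabelled astrocytes. Expression of these genes in the labelled cells or in labelled glia stays open, as untested.

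Many genes abundant elsewhere were missing from single Nkx2.1 libraries: of 1761 genes at 50 CPM or more in every SOM and VIP library, 1, 97 and 34 had 3 reads or fewer in Nkx2.1 replicates 1, 2 and 3. Thinned to 1 depth these libraries held 10235, 7870 and 9165 genes, and the other 6 held 9508 to 11370. Independent random loss is argued against, since 14 genes were missing from at least 2 libraries where independence gives 1.95, a ratio of 7.2. Loss that differs between genes was not tested, and the same ratio was 179 for SOM and 21.9 for VIP libraries. The first rests on 1 gene where independence gives 0.00558, and the second on 9 genes where it gives 0.411. A biological difference between the lines stays open, as untested, and no gene was missing from all 3 Nkx2.1 libraries.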
